A study of Mus musculus with 2 samples.

How the data were processed

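Transcript levels were measured by RNA sequencing in regulatory T cells (Tregs) sorted from the adipose tissue of C57BL/6 mice aged 4 months. There were 2 libraries, 1 per genotype: the Foxp3Cre control, and Hif1afl/fl;Foxp3Cre, in which Cre recombinase expressed with Foxp3, the lineage transcription factor of Tregs, acts on a floxed Hif1a gene. Samples were assigned to a genotype by the genotype label, and the count columns were assigned to samples by the library names in the sample descriptions. The labels do not say how many mice were pooled, which surface markers the sort used or which part of Hif1a is floxed. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with an Illumina TruSeq kit and reads were 150 bp paired-end. They state a mean read number per sample far above the totals of the table, which holds counts for its listed genes only.

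Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and edgeR were used, with a build named mm8; the edgeR version, the gene annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The authors deposited 1 table of 10219 genes with Ensembl gene IDs and symbols. The read counts per gene that the authors deposited are whole numbers and are not normalized. A mean of the 2 counts, which is a score here because it need not be a whole number, and a signed ratio of the raw counts stand beside them in the deposited table; the ratio equalled that of the raw counts within 1e-09 for 10219 genes and so carries no correction for depth. The authors' log2 fold change and log2 CPM, and their likelihood ratio statistic, a score, carry edgeR's column names, per the file headers. The authors' p-value and adjusted p-value come from the same test, per the file headers. When edgeR's likelihood ratio test was rerun here on the deposited counts with TMM scaling and a dispersion of 0, its log2 fold changes differed from the deposited ones by at most 9.77e-15 and its statistics by a relative 1.99e-12 at most, among statistics above 1. The deposited p-values therefore equal those of a test that allows for counting error only.

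The table holds no weakly counted gene. The lowest mean of the 2 counts was 50.5, and the lowest counts were 12 in the knockout and 14 in the control library, so genes with fewer counts in either library are not in the table, even if they were abundant in the other. The listed genes summed to 11337415 counts in the knockout and 13472317 in the control library. These totals are sums over the listed genes, not the sequencing depth. The rRNA genes Rn18s-rs5, mt-Rnr1 and mt-Rnr2 took 6.17% of the counts in the knockout and 5.58% in the control library. In 14 rows the symbol had been turned into a date; these genes were renamed by their Ensembl ID. Of the 10219 IDs, 10200 were found in the GENCODE M21 gene table. Because the build named in the notes differs from the GRCm38 build of that annotation, no coordinates are given. Counts of genes with near-identical copies, such as ferritin, ribosomal protein, hemoglobin and histocompatibility genes and receptor segments, and of genes that overlap another gene, are uncertain, because the counting of such reads is not known.

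Counts were scaled to counts per 1000000 counts of effective library size (CPM) by TMM (edgeR 4.0.16, R 4.3.3). The log2 ratio of knockout over control was computed on CPM + 0.5. A fold printed for a single gene is the ratio of the scaled counts without a pseudocount, and its 95% counting interval is the exact conditional binomial (Clopper-Pearson) interval (scipy 1.17.1). Such intervals cover counting error only; reads amplified by PCR are not independent molecules. With 1 library per genotype no spread between replicates can be estimated, so no p-value is given for a gene or list, apart from counts from the authors' p-values and from the same test under assumed spreads, and no difference between the genotypes has a replicate check. Genes were instead counted by a fixed rule of size, at least 2-fold, and gene lists were described by the median log2 ratio of their members and its percentile among 10000 random lists of the same size drawn from the listed genes in 20 bins of mean expression. A median's binomial interval is taken from the order of its members, and with fewer than 6 members their range stands in its place. The difference between 2 list medians was given a 95% bootstrap interval over 10000 draws of their members. The percentile describes these 2 libraries, and genes are not replicates.

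The size rule, 20 gene lists and 13 lists of cell type markers were fixed before the data were examined; 6 further lists were added afterwards and appear only in the closing section. The named genes were Hif1a, the 12 genes with the largest log2 ratio on CPM + 1 in each direction among genes of at least 5 CPM in 1 or both libraries, and up to 2 members at each end of every list; predicted genes, pseudogenes and receptor segments were to be skipped, and 0 had to be. Foxp3, Gata3, Tmem176b and the genes of the added lists were chosen after their values had been seen. A level of at least 1 CPM was required in 1 or both libraries, which removed 0 genes. On simulated counts for the same 10219 genes of this comparison, with 200 genes changed and no spread between animals, 99% of 100 genes changed by a log2 ratio of 1.5 and 100% of 100 genes changed by 3 were counted as at least 2-fold different, as were 0% of the unchanged genes, and 95.5% of the counting intervals held the true ratio.

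Alternatives were scaling by total count, by upper quartile, by median ratio (DESeq2 1.42.0) and on pan T cell markers, pseudocounts of 0.1 and 1, other level filters, other sizes of fold, the counting intervals, the authors' fold changes and adjusted p-values, and, for the lists, unmatched random lists, means and a correction for transcript length and GC content. Scaling on pan T cell markers, the length and GC correction and the assumed coefficients of variation were chosen after seeing the data.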

Results

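Adipose Tregs are Foxp3-expressing T cells that reside in fat. RNA sequencing compared these cells from a Foxp3Cre control and from a mouse line in which the same Cre acts on floxed Hif1a, the gene of the oxygen-regulated subunit of the transcription factor HIF-1. There was 1 library per genotype, so no value below has an error between animals and no difference has a replicate check. The 10219 listed genes held 11337415 counts in the knockout library and 13472317 in the control library. Across these genes the log2 levels of the 2 libraries correlated with a Pearson r of 0.867 and a Spearman rho of 0.871; genes are not independent replicates. The median absolute log2 ratio was 0.44.

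The targeted gene was examined first. Hif1a (ENSMUSG00000021109) stood at 780 CPM in the knockout library, from 8958 counts, and at 1273 CPM in the control library, from 16927 counts. It was therefore 1.63-fold lower in the knockout library, with a 95% counting interval of 1.59 to 1.68. The floxed part of the gene is not given in the labels, and counts over a whole gene include exons outside it, so this value is a limited check of the genotype. Counts from any cells without Foxp3 in the library would be included too, and macrophage markers had a median log2 ratio of 5.18. Among the 10 measured HIF pathway components, 2 were at least 2-fold lower and 0 at least 2-fold higher. Epas1, which encodes the related subunit HIF-2 alpha, was 2.26-fold lower (counting interval 1.48 to 3.54), from 31 and 81 counts. Arnt2, a dimerization partner, was 2.12-fold lower. Vhl, the substrate receptor for HIF degradation, was 1.61-fold higher (1.37 to 1.90). The list's median log2 ratio of -0.25 became -0.53 when scaled on pan T cell markers and -0.16 after a correction for transcript length and GC content. It lay at percentile 13.7 of random lists matched on expression.

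In the whole table, 1115 genes were at least 2-fold higher and 859 at least 2-fold lower in the knockout library, together 19.3% of the listed genes. At 16-fold or more, 56 genes were higher and 9 lower. Among the 12 genes with the largest difference towards the knockout library, Lyz2, Pf4 and Gpnmb belong to the fixed macrophage marker list. That list does not hold every gene that macrophages express: Cd36, outside it, is also abundant in macrophages. The cells that the counts of these 12 genes came from were not tested. Lyz2, which encodes lysozyme, had 452 CPM against 2.63 CPM, a fold of 172 (123 to 247). Cd36, a scavenger receptor and fatty acid transporter, had 274 CPM against 2.26 CPM, a fold of 122 (85.0 to 181). Slpi, a protease inhibitor, and the chemokine genes Ccl6 and Ccl9 were 116-fold, 115-fold and 96.4-fold higher. Pf4, Dab2, Fcgr2b, Clec4d, C3ar1, Clec4n and Gpnmb were between 39.0-fold and 103-fold higher. The control counts behind these 12 genes ranged from 16 for Dab2 to 190 for Clec4n.

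**Figure D1:**
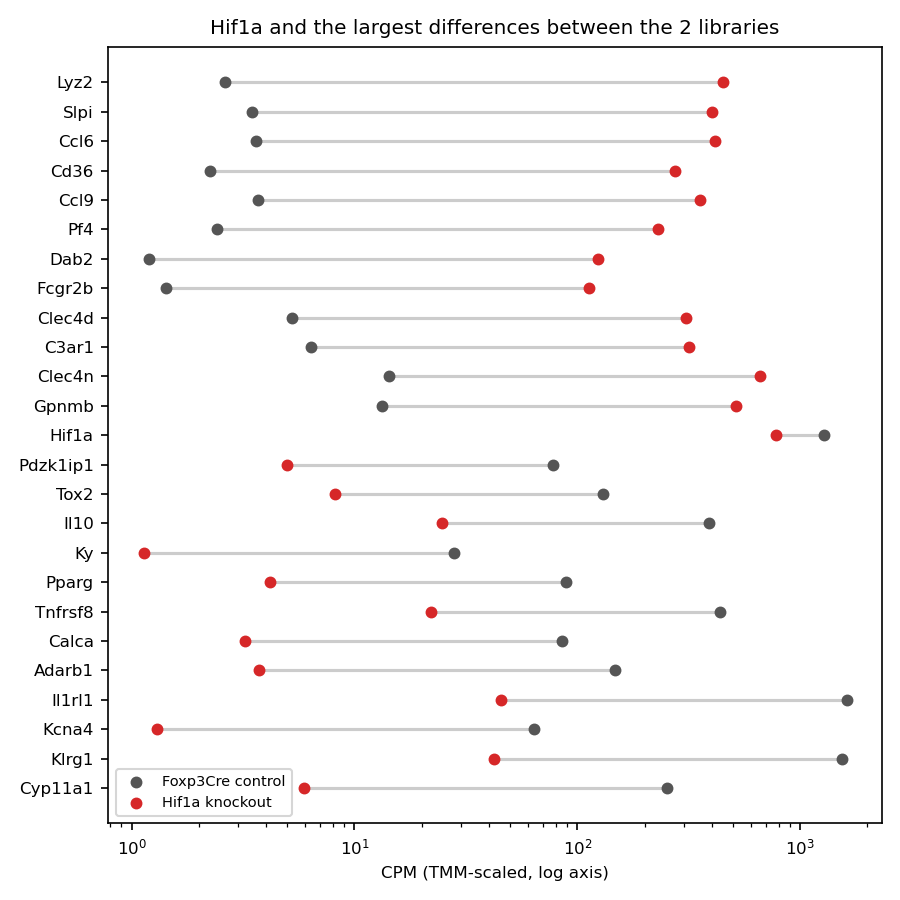
Levels of Hif1a and of the 12 genes with the largest difference in each direction, in CPM after TMM scaling on a log axis; each point is the single library of a genotype and the line joins the pair. Lyz2 lies at 452 CPM in the knockout and 2.63 CPM in the control library, and Il1rl1 at 45.4 CPM and 1616 CPM.

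Among the 12 genes with the largest difference in the other direction, Il1rl1, Klrg1, Pparg and Il10 belong to the fixed list of adipose Treg genes. Il1rl1, which encodes the IL-33 receptor ST2, had 45.4 CPM in the knockout and 1616 CPM in the control library and was 35.6-fold lower (32.6 to 38.9). Klrg1, a marker of differentiated lymphocytes, had 42.1 CPM against 1542 CPM and was 36.6-fold lower (33.4 to 40.1). Pparg, the nuclear receptor associated with adipose Tregs, was 21.3-fold lower (15.9 to 29.0), and the cytokine gene Il10 was 15.7-fold lower (13.9 to 17.8). Cyp11a1, the enzyme that starts steroid hormone synthesis from cholesterol, was 42.7-fold lower (33.6 to 55.1). Kcna4, a potassium channel gene, was 48.9-fold lower, from 15 knockout counts, and Adarb1, an RNA-editing enzyme gene, was 39.6-fold lower. Calca, Tnfrsf8, Tox2, Ky and Pdzk1ip1 were between 15.7-fold and 26.5-fold lower. When the libraries were scaled so that the pan T cell markers had a median log2 ratio of 0, which moved the median of all genes by -0.28, the split changed from 1115 higher and 859 lower genes (56.5% higher) to 784 higher and 1435 lower (35.3% higher).

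As a group, the adipose Treg genes were lower in the knockout library. Of 27 measured members, 20 were at least 2-fold lower and 2 at least 2-fold higher, and the median log2 ratio of -1.38 lay below each of the 10000 random lists. The 2 higher members were Cd36 and Gata1, the latter 6.74-fold higher from 99 and 17 counts; Cd36 is also abundant in macrophages, whose markers had a median log2 ratio of 5.18. The T helper 2 list, which shares Il1rl1, Pparg and Gata3 with the adipose list, had 5 of 7 measured members at least 2-fold lower and a median of -2.14, at percentile 0. That median's binomial interval ran from -5.14 to 0.60. Its members Il4ra and Stat6 had log2 ratios of 0.10 and 0.60, and Il4ra changed sign to -0.18 when scaled on pan T cell markers. The 23 measured Treg core genes went both ways, with 7 at least 2-fold higher, 7 at least 2-fold lower and 9 within 2-fold. Il2ra, the high-affinity IL-2 receptor chain, was 7.14-fold lower (6.97 to 7.32), at 608 CPM against 4346 CPM, and Tnfrsf9 was 3.65-fold lower. Gpr83 and Izumo1r were 17.6-fold (13.1 to 24.1) and 6.93-fold higher. The median of the core list was -0.52 (binomial interval -1.15 to 1.12; -0.80 when scaled on pan T cell markers), at percentile 0.29, whereas its mean was 0.0017. Foxp3 itself was 2.24-fold lower (2.02 to 2.48).

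Genes of naive and lymphoid-homing T cells were higher in the knockout library. Among 14 measured members, 11 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.10 that exceeded each random list. Tcf7, a transcription factor of naive and memory T cells, had 223 CPM against 7.0 CPM and was 31.9-fold higher (25.9 to 39.7). Bach2, a repressor of effector differentiation, was 18.0-fold higher (13.6 to 24.3). Il7r and Il6st differed by less than 2-fold, at log2 ratios of -0.33 and 0.08, the latter -0.20 when scaled on pan T cell markers. In the T helper 1 list, 6 of 10 measured members were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 1.25 at percentile 100. Gzmk was 19.1-fold higher from 264 and 16 counts, and the chemokine receptor gene Cxcr3 was 4.37-fold higher, while Il18rap, an IL-18 receptor chain, was 2.91-fold lower. For T helper 17 genes, 5 of 14 were measured and 4 were at least 2-fold higher (median 1.25, percentile 99.7): these were Il6ra, Ahr, Tmem176a and Tmem176b, which myeloid cells also express. Macrophage markers were higher in the same library, by a median of 5.18.

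**Figure D2:**
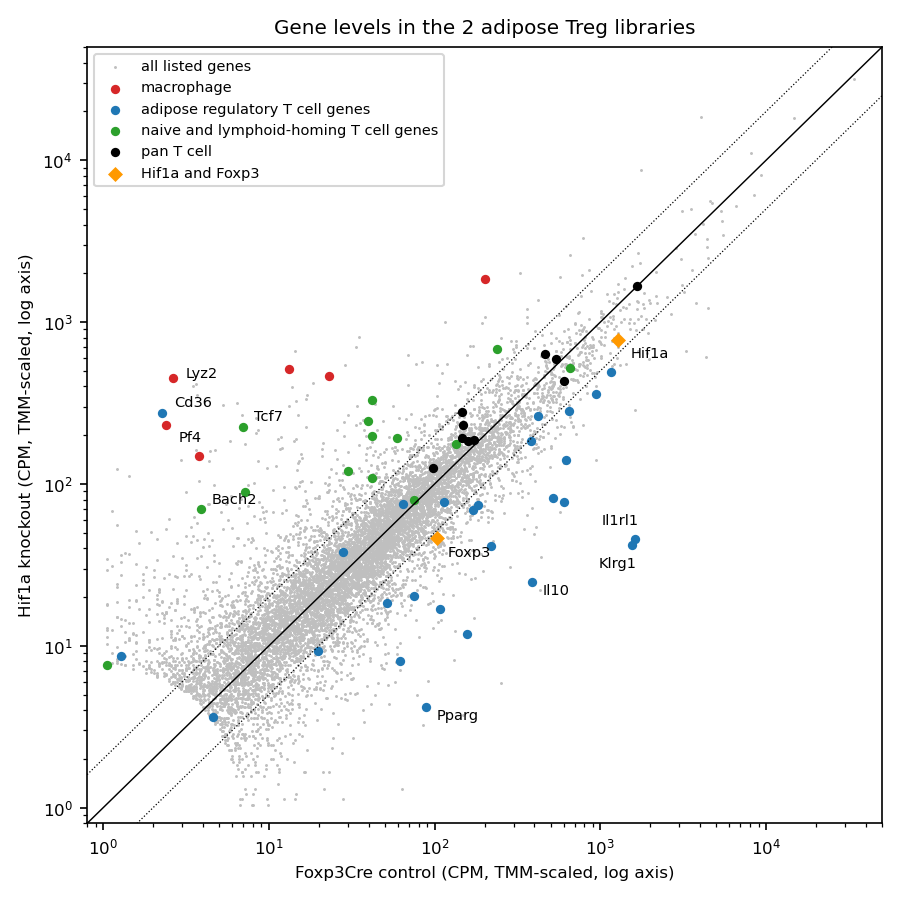
Levels of the 10219 listed genes in the control library (horizontal axis) and the knockout library (vertical axis), in CPM after TMM scaling on log axes; the solid line marks equal levels, the dotted lines 2-fold differences, and colours mark 4 of the fixed lists and, as diamonds, Hif1a and Foxp3. Macrophage markers lie above the upper dotted line, most adipose Treg genes below the lower one, and the empty corner at low levels reflects the low-count limit of the table.

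Markers of the sorted lineage and of other cells were compared in the same way. All 10 pan T cell markers were within 2-fold, from Trac at a log2 ratio of -0.48 to Lck at 0.91, with a median of 0.28. All 6 measured macrophage markers, of 17 in the list, were at least 2-fold higher in the knockout library, with a median of 5.18. Ctss, which encodes cathepsin S, was the most abundant of them at 1849 CPM against 200.0 CPM, a fold of 9.24 (8.88 to 9.63), and Cd68 stood at 461 CPM against 23.0 CPM (counting interval of the fold 17.8 to 22.5). Of 9 measured dendritic cell markers, 7 were at least 2-fold higher, among them H2-Ab1 and H2-Aa at 4.01-fold and 3.94-fold. Flt3 had a log2 ratio of 0.99, and Xcr1 was 3.37-fold lower. Whether the counts of the dendritic cell list came from dendritic cells or from macrophages was not tested. The 3 measured markers of natural killer and group 2 innate lymphoid cells were Tyrobp, Arg1 and Klrk1; they were 30.5-fold, 13.2-fold and 3.65-fold higher, and myeloid cells also express Tyrobp and Arg1. Of 3 measured B cell markers, Ighm was 2.27-fold higher and Cd79b and Igkc had log2 ratios of -0.31 and -0.27; the median of -0.27 became -0.54 when scaled on pan T cell markers and -0.046 after the length and GC correction, and the mean was 0.20. The 5 measured erythroid genes were within 2-fold, with a median of 0.60, which became 0.32 when scaled on pan T cell markers and 0.82 after the length and GC correction. Of 3 measured CD8 T cell markers, Klrd1 was 9.75-fold higher, from 118 and 14 counts, Gzma was 2.28-fold lower and Cd8b1, the median, had a log2 ratio of -0.23, or -0.50 in that scaling and -0.12 after that correction, and the mean was 0.46. Of 6 measured stromal markers, 3 were at least 2-fold higher and the median was 0.72, or 0.45 in that scaling. Dpp4 and Thy1 had log2 ratios of 3.99 and 1.97. Ly6a, the most abundant at 2499 CPM against 4477 CPM, and Mfap5 had -0.84 and -0.49. With members on both sides of 0, the median does not measure stromal content. Whether the counts of these members came from stromal cells or from the sorted T cells was not tested. Adipocyte markers were represented by Adipor2 and Lipe, at log2 ratios of -0.12 and 0.65, and neutrophil markers by Mmp9, at -0.35. Endothelial and mesothelial markers were represented by Pecam1, Kdr and Krt18, at 0.50, 3.73 and 3.56. Of the 7 mast cell markers, 0 were measured.

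HIF-1 target genes outside glycolysis did not move together. Of 23 measured members, 8 were at least 2-fold lower and 2 at least 2-fold higher, and 13 were within 2-fold. Egln3, a prolyl hydroxylase gene induced by HIF, was 9.44-fold lower (7.06 to 12.9), and Ero1l, an oxidase of the endoplasmic reticulum, was 9.21-fold lower (8.26 to 10.3). Hmox1, which encodes heme oxygenase and is abundant in macrophages, was 5.91-fold higher (5.51 to 6.36), and P4ha1 was 2.58-fold higher. The list's median was 0.14, at percentile 81.6, its mean was -0.39, and its median became -0.13 when scaled on pan T cell markers. Macrophage markers had a median of 5.18 in the same comparison.

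Genes of glucose and mitochondrial metabolism were mostly lower in the knockout library, by less than 2-fold. Among 20 measured glycolysis genes, 14 had lower and 6 higher levels, 5 were at least 2-fold lower and 3 at least 2-fold higher, and the median of -0.55 (binomial interval -0.89 to 0.07) lay at percentile 0.22, with a mean of -0.33. Aldoa, which encodes aldolase A, was 2.43-fold lower (2.36 to 2.51) and the monocarboxylate transporter gene Slc16a1 2.45-fold lower, whereas Pdk1 and Eno2 were 2.25-fold and 2.38-fold higher. Of 45 oxidative phosphorylation genes, 43 had lower levels, 4 of them by at least 2-fold, with a median of -0.52 at percentile 0.01. Atp5g1 and Uqcrq, subunits of ATP synthase and complex III, were 3.25-fold and 3.01-fold lower, and Sdha was at a log2 ratio of 0.13, which became -0.15 when scaled on pan T cell markers. The tricarboxylic acid cycle list had a median of -0.38, at percentile 1.7, with Suclg2 2.46-fold and Mdh2 2.01-fold lower. Fatty acid oxidation genes had a median of -0.29, at percentile 2.51, with Acadvl and Etfb 2.98-fold and 2.99-fold lower. Scaled on pan T cell markers, the medians of glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation became -0.83, -0.80, -0.66 and -0.57. The macrophage markers, with a median of 5.18, were higher in the same library.

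Cholesterol synthesis genes were lower as a group. All 20 measured members had lower levels in the knockout library, 12 of them by at least 2-fold, and the median of -1.20 lay below each random list. Hsd17b7 was 6.10-fold lower (4.58 to 8.27) and Idi1 4.28-fold lower (3.66 to 5.02), while Mvk and Pmvk had counting intervals that included no difference. Lipid uptake and storage genes went both ways, with 4 of 16 at least 2-fold higher and 3 at least 2-fold lower. Cd36 and Apoe, both abundant in macrophages, were 122-fold and 8.65-fold higher, whereas Dgat2, an enzyme of triglyceride synthesis, was 13.2-fold lower (11.1 to 15.8) and Acaca 2.81-fold lower. That list had a median of -0.04 and a mean of 0.40, beside a macrophage marker median of 5.18. Its median became -0.32 when scaled on pan T cell markers, -0.0046 with total-count scaling and -0.00069 after the length and GC correction.

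**Figure D3:**
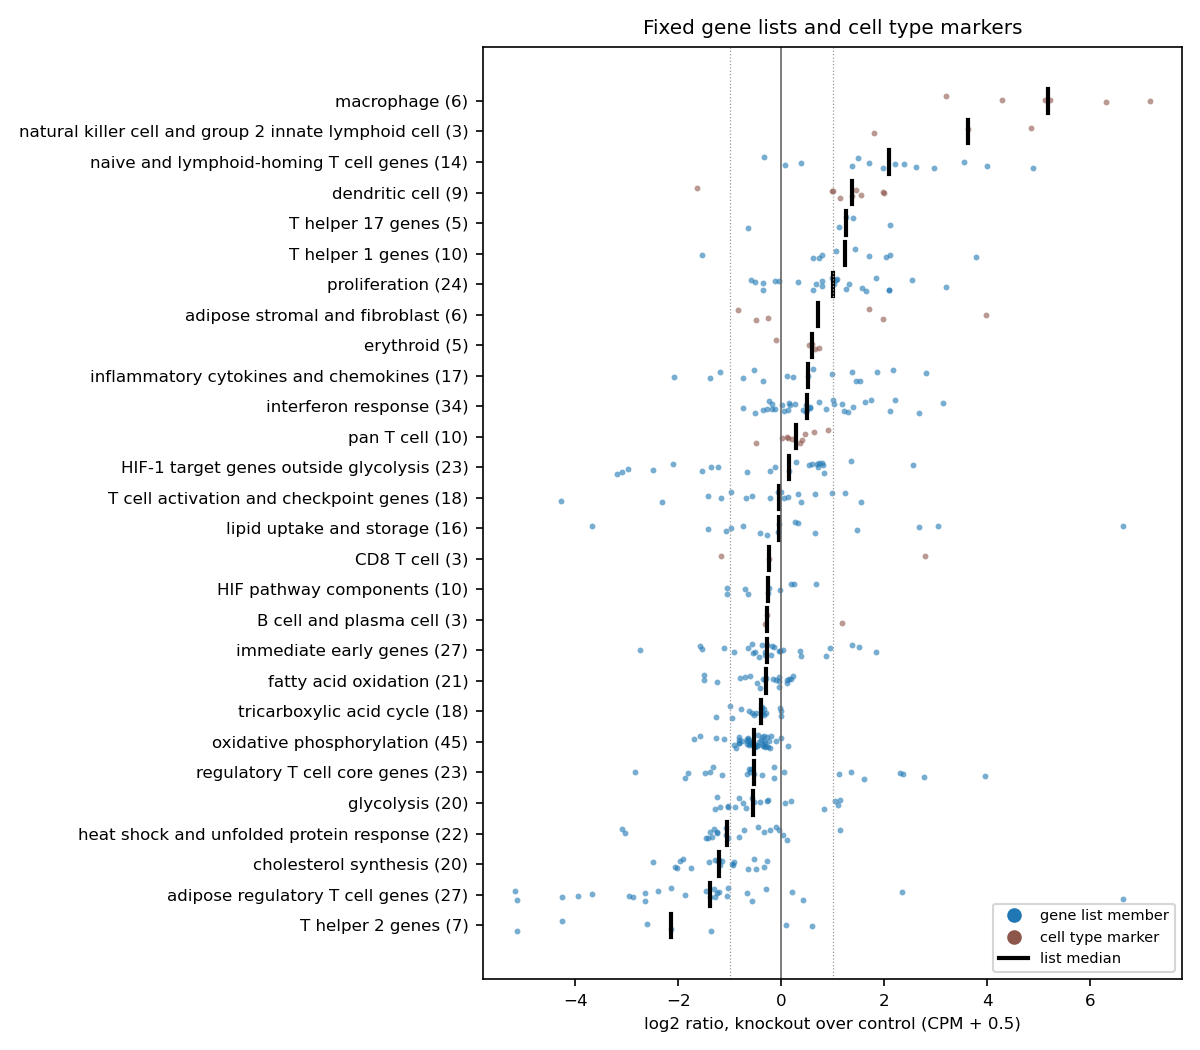
Log2 ratio of knockout over control for every measured member of the fixed gene lists (blue) and cell type marker lists (brown) with at least 3 measured members; black bars are list medians, numbers in brackets give the measured members, and dotted lines mark 2-fold. The macrophage list has the highest median, 5.18, and the T helper 2 and adipose Treg lists the lowest, at -2.14 and -1.38.

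Several response programmes also differed between the libraries. Of 34 interferon response genes, 12 were at least 2-fold higher and 0 at least 2-fold lower (median 0.50, percentile 100), led by Ifi44 at 9.17-fold and Oas2 at 6.47-fold; Cxcl10 was 1.67-fold lower. Of 24 proliferation genes, 12 were at least 2-fold higher and 0 at least 2-fold lower (median 1.01, percentile 100). The mitotic genes Ube2c and Ccna2 were 11.6-fold and 8.02-fold higher, from 23 and 15 control counts, and the S phase genes Tyms and Mcm3 were 1.51-fold and 1.43-fold lower. Heat shock and unfolded protein response genes were lower in 19 of 22 cases, 12 by at least 2-fold (median -1.04, percentile 0), with Chac1 and Asns 8.74-fold and 8.53-fold lower and Ddit3 2.2-fold higher. Among inflammatory cytokines and chemokines, 6 of 17 were at least 2-fold higher and 3 at least 2-fold lower (median 0.52, binomial interval -0.53 to 1.46, percentile 99.5). Ccl2 and Il1b, which macrophages also produce, were 7.11-fold and 4.59-fold higher, and Lif and Cxcl2 were 4.70-fold and 2.60-fold lower. Immediate early genes (median -0.27, percentile 10.6) included Myc and Cd69, 6.76-fold and 2.97-fold lower, and Egr2 and Dusp2, 4.10-fold and 2.88-fold higher. T cell activation and checkpoint genes (median -0.03, percentile 62.3) included Tnfrsf8, 19.7-fold lower, and Gzmb, 4.95-fold lower at 660 CPM against 3266 CPM; Cd27 and Cd200 were 2.95-fold and 2.37-fold higher. Scaled on pan T cell markers, the medians became 0.21 for interferon, 0.23 for inflammatory, -0.55 for immediate early and -0.31 for activation and checkpoint genes. The activation and checkpoint list had a mean of -0.35, and its median changed sign to 0.0034 with total-count scaling and to 0.0029 after the length and GC correction. The macrophage marker median was 5.18 in the same comparison.

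In the authors' deposited table, 7487 genes, 73.3% of those listed, have an edgeR adjusted p-value under 0.05, 3749 of them higher and 3738 lower in the knockout library. With a log2 fold change of at least 1 as well, the authors' deposited table has 1168 higher and 896 lower genes. These p-values equal those of a test with a dispersion of 0, so they compare the 2 libraries and not the genotypes.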

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

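Scaling on pan T cell markers, the length and GC correction and the assumed coefficients of variation were chosen after seeing the data. The counts of 1115 higher and 859 lower genes became 2067 and 1886 at 1.5-fold and 350 and 161 at 4-fold, and 1435 genes were lower when scaled on pan T cell markers; under the other scalings, pseudocounts, level filters, counting intervals and the authors' values both stayed within 1.5 times. The log2 ratio of Hif1a, -0.71, became -0.67 with total-count scaling and -0.99 on pan T cell markers. Of 280 alternative values of the list medians, 273 stayed within the median's binomial interval. This is a weak check. Total-count, upper-quartile and median-ratio scaling moved the median of all genes by at most 0.038, so they could hardly move a list out. Wide intervals also hold changes of sign: the HIF-1 target list, with a median of 0.14 (-1.36 to 0.72) and a mean of -0.39, counts as within. On pan T cell markers the medians became -0.80 for oxidative phosphorylation, -0.66 for the tricarboxylic acid cycle, -0.55 for immediate early genes, -0.54 for B cell markers and -5.97e-05 for pan T cell markers, which that scaling sets to about 0. The Treg core list reversed from a median of -0.52 to a mean of 0.0017, because its members lie on both sides, and the erythroid median became 0.82 after the length and GC correction; the cause was not tested. With unmatched random lists, 28 of 28 percentiles stayed on the same side of the limits of the central 95%. None of the 834 alternative values of single named genes reversed a difference of at least 2-fold, but none could. The scalings moved the median log2 ratio of all genes by at most 0.28 in size, and a pseudocount keeps the sign. The sign changed under 1 or more scalings for Hif1an, Ndufa4, Sdha, Ogdh, Dlst, Acadl, Acaa1a, Il4ra, Il6st, Bag3 and Cd2, whose log2 ratios were at most 0.25. The authors' 7487 genes with an adjusted p-value under 0.05 became 4272, 1641 and 223 in edgeR's same test with an assumed coefficient of variation of 0.1, 0.2 and 0.4, because a larger assumed spread calls fewer genes. No paired analysis was possible because each genotype has 1 library, and no library could be left out. A filter at a mean of 1 CPM removes nothing from this table, so it tests nothing, though its values are among the 280 for list medians. Genes under the table's count limit were not analysed here.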

Other observations

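The lists in this paragraph and the next and all tests below were chosen after the data were seen. Genes of serine, one-carbon and amino acid synthesis were lower in the knockout library: 15 of 17 measured members were at least 2-fold lower, with a median log2 ratio of -2.02. Bcat1, which transaminates branched-chain amino acids, was 14.9-fold lower, Psat1 of the serine pathway 7.55-fold, Shmt2 of mitochondrial one-carbon metabolism 6.50-fold and Phgdh 4.08-fold. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 10 were at least 2-fold lower and 0 at least 2-fold higher (median -1.06), with Tars 3.72-fold and Lars 3.62-fold lower. Amino acid transporter genes had 5 of 10 members at least 2-fold lower, among them Slc1a5 at 3.84-fold and Slc7a5 at 3.46-fold, while Slc7a11, the cystine transporter, was 9.19-fold higher. Of 78 genes with a cytosolic ribosomal protein name (Rps or Rpl with a number), 74 had lower levels, 6 of them by at least 2-fold (median -0.50). The name rule also took in Rps19bp1, a binding protein gene, and ribosomal protein-like genes such as Rpl36al and Rpl7l1. Reads shared with pseudogenes make single members uncertain. The macrophage markers had a median of 5.18 in the same comparison.

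T cell receptor beta variable segments were higher in 13 of 14 cases, 9 by at least 2-fold (median 1.33), with Trbv3 4.80-fold higher and Trbv15 at a log2 ratio of -0.32. These segments resemble each other and reads can be split between them. The ferritin genes Fth1 and Ftl1 together took 2.74% of the counts in the knockout and 0.572% in the control library.

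The macrophage markers were the list with the highest median in the knockout library, 5.18. Counting noise is argued against, because the lowest counting bound of the fold over the 6 markers was 8.88. A lower share of T cells alone would raise all other cell types alike. For the measured markers, the highest log2 ratio among B cell and erythroid markers was 1.18 and the lowest among macrophage markers 3.21. The pan T cell markers had a median of 0.28. These values were known when the comparison was chosen and the level per T cell was not measured, so it cannot decide. Only 3 of 11 B cell and 5 of 7 erythroid markers were measured, because genes with few counts in the control library are not listed. The comparison does not set the macrophage list apart from members of every other list. Dpp4 (stromal list), Kdr (endothelial list) and Krt18 (mesothelial list) had log2 ratios of 3.99, 3.73 and 3.56. The cells that their counts came from were not tested. Arg1 and Tyrobp (innate lymphoid list) had 3.63 and 4.85, but myeloid cells also express them, so they cannot stand for another cell type. Other members of these lists rose less or were lower: the stromal median was 0.72, and Pecam1 (endothelial) had 0.50. Macrophages or monocytes among the knockout cells stay open: of 22 measured abundant macrophage transcripts outside the marker list, 20, or 90.9%, were at least 2-fold higher (list median 2.52), with Fth1 at 18425 CPM against 4033 CPM, but that list was drawn up with some of its values seen and so cannot decide. A sort for Tregs is meant to remove such cells, but its gate is not given in the labels, and an effect of the genotype on the Tregs or on the surrounding macrophages was not tested, since each genotype has 1 library.

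Adipose Treg genes were lower while naive and lymphoid-homing genes were higher. With other cells in place of Tregs as the whole cause, no adipose gene would fall further than Foxp3, which was 2.24-fold lower. Of the 27 adipose genes, 13 had counting intervals wholly below that of Foxp3. These intervals cover counting error only, so the comparison holds for these 2 libraries. It also assumes a like Foxp3 level per Treg in both. The values were known when the comparison was chosen and the Foxp3 level per Treg was not measured, so it cannot decide. A linear bias with transcript length and GC content is argued against as the whole cause. The adipose median was -1.36 after that trend was removed and -1.38 before. Bias of another form was not tested. Other cells in place of Tregs, a larger share of lymphoid-type Tregs in the knockout sample and an effect of Hif1a loss within resident Tregs stay open. The share of lymphoid-type Tregs and the effect of Hif1a loss were not tested.

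Lower levels were found for 14 of 20 glycolysis, 43 of 45 oxidative phosphorylation and 20 of 20 cholesterol synthesis genes; 3 glycolysis genes were at least 2-fold higher, and the interval of that list's median, -0.89 to 0.07, includes 0. Dilution of T cell RNA by RNA of other cells would lower the pan T cell markers too, at a constant level per cell. Their median was 0.28, and each list median lay below it. The upper bootstrap bounds of the difference, over genes, were -0.30, -0.55 and -1.08 in the same order. These medians were known beforehand and the level per T cell was not measured, so the comparison cannot decide. A linear bias with transcript length and GC content is argued against as the whole cause, because the trend removed from these lists had a median with a lower bound of -0.097, -0.15 and -0.042, against list medians of -0.55, -0.52 and -1.20. After its removal the lists lay at percentiles 0.11, 0.03 and 0. Dilution, a different activation state or mix of Tregs, and the genotype itself stay open. The activation state, the mix of Tregs and the genotype were not tested.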
